A study of Danio rerio with 6 samples.

How the data were processed

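RNA was extracted from pools of whole AB zebrafish embryos, and stranded total RNA libraries were made after removal of ribosomal RNA, per the labels' protocols. The reads were aligned with TopHat 1.4.0 and compared with Cuffdiff 2.1.1 on Zv9 (danRer7), per the submitters' processing notes. The deposited table holds, for 32571 Ensembl gene IDs and 5 comparisons, the FPKM of both groups as Cuffdiff gives it, per the file headers. It also holds the authors' p-value and q-value, a test status and a yes or no call, per the file headers. How FPKM were scaled between libraries, whether counting used strand and which annotation release was used are not given in the sources used here. The series design states triplicates; the columns give 1 value per group, so no spread between replicates, leave-one-out fit or test was computed here, and the depth behind each value is unknown. Whether the triplicates were separate clutches is not stated, so the authors' q-values may measure technical spread only. The smallest p in the table is 5e-05, and q below 0.05 matched the authors' own calls for every gene.

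Groups that stand in several comparisons have nearly the same FPKM in each: 81% to 84.6% of values were identical, and 12 rows differed by more than 1.5-fold. Each comparison uses the FPKM deposited with it. Fold-change and test-statistic columns were not used, since part of their cells hold spreadsheet errors. Symbols are those of the table; 18 had been turned into dates, 504 rows have none and 5144 rows share a symbol with another. Of the IDs, 20899 were found in a reference list of names, which was used to find list members whose symbol the table lacks. Loci are printed as the table gives them, and the base from which their starts count was not checked. Since 7140 rows (21.9%) share a locus with another, values of overlapping genes, gene copies and histone genes are uncertain.

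From the FPKM, log2 of (FPKM + 1) ratios were computed for genes at an FPKM of at least 1 in either group, which understates changes of low genes. Changes were called from the authors' q under 0.05 in the deposited table, and sizes from a 2-fold difference. No p-value was computed across genes. A list's median is described by its percentile among 10000 random lists of the same size, drawn within 20 bins of mean expression. List members are counted as rows, so a symbol on several rows enters with each of its rows. Counts adjusted over the list alone are Benjamini-Hochberg adjustments of the deposited p-values of list members. Choices made before the data were examined were the comparisons of control 6 hpf with 2 hpf, of miR-430 MO and CNOT7-DN with control 6 hpf, of amanitin and of control 6 hpf with control B, 22 gene lists, the cleared and zygotic sets and the rule for named genes. That rule takes the 8 largest rises and falls with q under 0.05 and an FPKM of at least 5 (3 each way, without q, between the controls), leaving out placeholder names, symbols on several rows and small RNAs, plus up to 4 members per list and cnot7 and cnot8. The comparison of amanitin with 2 hpf was added later. The pattern of names by which the rule for named genes leaves out small RNAs was corrected after first results were seen.

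The lists are zygotic patterning transcription factors, mesendoderm and Nodal pathway, BMP and ventral genes, enveloping layer, yolk syncytial layer, germ plasm, oocyte and egg genes, maternal pluripotency factors, reported miR-430 targets, CCR4-NOT, decapping and decay factors, ribosomal proteins, oxidative phosphorylation, replication-dependent histones, cell cycle, p53 response, heat shock and interferon response, later-stage markers, adult tissue markers, solute carriers, translation factors and zinc finger genes. Alternatives were pseudocounts of 0.1 and 5, an FPKM minimum of 5 or none, folds of 1.5 and 4, rescaling to equal sums, centring on the median gene or on ribosomal protein genes, unique symbols only, and the other 6 hpf control. Chance from the shared control was simulated 100 times from the differences between the controls.

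The scripts were tested on simulated FPKM with a known set of genes changed and noise as between the controls. In the simulated miR-430 MO comparison, over 15118 genes, the 2-fold rule called 56% of genes raised 2-fold, 94% raised 4-fold and 100% raised 8-fold, and 1.7% of unchanged genes. Genes lowered 2-fold were called less often, 36% in that comparison, 32% for CNOT7-DN and 26% for amanitin. Of genes raised 2-, 4- and 8-fold, the rule called in the simulated CNOT7-DN comparison 42%, 98% and 100%, and in that of amanitin, over 15252 genes, 40%, 94% and 100%. The simulated miR-430 MO and CNOT7-DN comparisons start from the same control and noise. They differ only by the random draw of 50 genes per fold, so their shares do not describe the treatments. Between the real controls 3.91% of genes were at least 2-fold apart, more than the simulated share of unchanged genes called. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used. Codon usage, 3 prime UTR length and miR-430 seed sites need transcript sequences and were not analysed here.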

Results

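Transcript levels were measured by RNA sequencing of whole zebrafish embryos of the AB strain in 6 groups, each with 1 deposited value per gene. Control embryos were taken at 2 hours post fertilisation (hpf), when the embryo still runs on RNA laid down by the mother, and at 6 hpf, after transcription of its own genome has begun. At 6 hpf there were also embryos injected with a morpholino (an antisense oligonucleotide) against the microRNA miR-430 (miR-430 MO), embryos injected with CNOT7-DN, which the series design describes as inhibition of the deadenylase CNOT7, and embryos injected with alpha-amanitin, an inhibitor of RNA polymerase II. The amanitin group had a 6 hpf control of its own, called control B. The table listed 32571 genes. Summed FPKM (fragments scaled for gene length and sequencing depth) was 726913 at 2 hpf, 1035854 in control 6 hpf, 1010944 in miR-430 MO, 1018141 in CNOT7-DN, 963040 in control B and 747626 in amanitin. Between 12962 (amanitin) and 15252 (control B) genes had an FPKM of at least 1. Read depth is unknown and no value per replicate was analysed here, so no value below carries a standard deviation. A gene is said to have risen, fallen or changed only where its q-value in the authors' deposited table was under 0.05. Sizes are log2 of the ratio of FPKM + 1. The largest rises and falls are named among genes at an FPKM of at least 5 whose symbol stands on 1 row, with small RNAs and placeholder names left out.

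The gene named by the CNOT7-DN label was examined first. The row of cnot7 (ENSDARG00000032116, chromosome 14, 31283386 to 31294483 on Zv9), a catalytic subunit of the CCR4-NOT deadenylase, stood at 12850.3 FPKM in CNOT7-DN, against 7.4 in control 6 hpf, 12.6 in miR-430 MO, 4.55 in control B, 24.6 in amanitin and 26.9 at 2 hpf. The row does not separate injected RNA from that of the embryo. Its paralog cnot8 stood at 199.6 FPKM at 2 hpf, 145 in control 6 hpf, 143 in miR-430 MO, 183 in CNOT7-DN, 111 in control B and 326 in amanitin. No row gives the activity of miR-430, so the morpholino label has no such check.

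The controls at 6 hpf are separate groups and were not tested against each other. Their difference is the only one here between untreated groups given the same stage. Control B was at least 2-fold higher than control 6 hpf for 371 genes and at least 2-fold lower for 248 of 15826 considered, which is 3.91%. Among the differing genes 59.9% were higher, or 71.6% after rescaling to equal sums. The heat-inducible chaperone hsp70l was at 22.1 FPKM in control 6 hpf and 1.52 in control B, and the patterning factors otx1b and her3 were at 0.612 and 6.6 and at 5.24 and 26.6. The transcription factor runx2b was at 2.11 and 16.9, and msgn1, a gene of the paraxial mesoderm, at 15.6 and 41.6. Oocyte genes lay lower in control B (median -0.34) and zygotic patterning factors higher (0.31).

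From 2 to 6 hpf part of the RNA of the egg fell and genes of the embryo's own tissues rose. The largest rises included genes of the outer epithelium and the yolk syncytial layer, the extraembryonic layer over the yolk. The keratin krt18 (ENSDARG00000018404, chromosome 23, 10454076 to 10457982) rose from 0.742 to 1636 FPKM, the keratin krt4 from 0.278 to 821 and the apolipoprotein apoeb from 0.909 to 1622. The gene akap12b rose from 0.889 to 907, asb11 from 0.24 to 645, stm from 0.511 to 777 and the small heat-shock protein hspb1 from 2.0 to 1203. The largest falls included the claudin cldng (1373 to 97.8 FPKM), the egg deadenylation adaptor btg4 (618 to 58.4; ENSDARG00000035171, chromosome 5, 59273721 to 59275804), the meiotic kinase mos (170.2 to 15.3), the metallothionein mt2 (809 to 77.4), cdca9 (253 to 23.2), sinup (312 to 25.4), gbgt1l1 (41.3 to 2.45) and CYSTM1 (204 to 17.6). In the authors' deposited table q for these genes lay between 0.0001 and 0.00115.

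Lists fixed before the data were examined moved as groups. Centring adds the same amount to each log2 ratio of a comparison, which here is 0.59 for centring on the median gene and -0.95 for ribosomal protein genes. Zygotic patterning transcription factors had a median of 5.34. Of 31 measured, 22 rose and 0 fell in the authors' deposited table (22 and 0 adjusted over the list alone). The T-box factor tbx16 rose from 0.0651 to 194 FPKM and sox3 from 1.08 to 299. Mesendoderm and Nodal genes had a median of 4.40. Of 36 measured, 21 rose and 0 fell in the authors' deposited table (21 and 0 adjusted over the list alone). Among them were the T-box factor ntla, from 0.193 to 189 FPKM, and the endoderm factor sox32, from 0.233 to 156. BMP and ventral genes had a median of 3.22. Of 15 measured, 9 rose and 1 fell in the authors' deposited table (9 and 1 adjusted over the list alone). The BMP target id1 rose from 22.2 to 931 FPKM. Enveloping layer genes had a median of 6.31. Of 16 measured, 12 rose and 1 fell in the authors' deposited table (12 and 1 adjusted over the list alone). Yolk syncytial layer genes had a median of 6.10. Of 13 measured, 7 rose and 0 fell in the authors' deposited table (7 and 0 adjusted over the list alone). The lipid transfer protein mtp rose from 0.171 to 286 FPKM. Some members near 0 FPKM at 2 hpf missed the authors' test. One of them was sox19a, named after its values were seen, at 0.0628 and 425 FPKM (q = 0.195 in the authors' deposited table).

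Genes of the egg went the other way. Oocyte and egg genes had a median of -1.71. Of 34 measured, 1 rose and 30 fell in the authors' deposited table (1 and 30 adjusted over the list alone). The egg gene zar1l fell from 496 to 56.6 FPKM. Germ plasm genes had a median of -1.71. Of 13 measured, 0 rose and 12 fell in the authors' deposited table (0 and 12 adjusted over the list alone). The RNA-binding protein dazl fell from 209 to 34.4 FPKM, buc, the organiser of the Balbiani body, from 546 to 96.5, and the Tudor domain gene tdrd6 from 177 to 31.6. Maternal pluripotency factors had a median of 1.06. Of 7 measured, 4 rose and 2 fell in the authors' deposited table (4 and 2 adjusted over the list alone). Of these pou5f1 rose from 281 to 755 FPKM, while sox19b fell from 289.9 to 83.1 and eomesa from 31.3 to 11.7.

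Lists of general machinery differed in their medians. Ribosomal protein genes had a median of 0.95. Of 84 measured, 77 rose and 1 fell in the authors' deposited table (77 and 1 adjusted over the list alone). Nuclear genes of oxidative phosphorylation had a median of -0.63, or -0.038 centred on the median gene. That list lay at percentile 8.34 of random lists, so it was not lower than such lists usually are. Of 77 measured, 6 rose and 47 fell in the authors' deposited table (6 and 47 adjusted over the list alone). One of them, atp5l, fell from 218 to 40 FPKM. Replication-dependent histone genes had a median of 1.78. Of 8 measured, 7 rose and 1 fell in the authors' deposited table (7 and 1 adjusted over the list alone). Cell cycle genes had a median of -0.19, or 0.40 when centred on the median gene, and an uncentred mean of 0.67. Of 42 measured, 15 rose and 20 fell in the authors' deposited table (15 and 20 adjusted over the list alone). Cyclin D1, ccnd1, rose from 0.832 to 544 FPKM and cyclin E2, ccne2, from 0.726 to 131. The same centring turned the sign for the next lists. CCR4-NOT genes had a median of -0.22, or 0.37 centred. Of 24 measured, 6 rose and 10 fell in the authors' deposited table (6 and 10 adjusted over the list alone). Decapping, decay and silencing factors had a median of -0.055, or 0.54 centred. Of 41 measured, 12 rose and 17 fell in the authors' deposited table (12 and 17 adjusted over the list alone). Translation factors had a median of -0.029, or 0.57 centred. Of 73 measured, 24 rose and 29 fell in the authors' deposited table (24 and 29 adjusted over the list alone). Solute carriers had a median of -0.54, or 0.054 centred. Of 226 measured, 41 rose and 120 fell in the authors' deposited table (41 and 120 adjusted over the list alone). Zinc finger genes had a median of -0.46, or 0.14 centred. Of 118 measured, 19 rose and 69 fell in the authors' deposited table (19 and 69 adjusted over the list alone).

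Over all genes, 3228 rose and 8017 fell of 15504 tested in the authors' deposited table, and 2027 and 4644 of these differed at least 2-fold. By size alone 3037 genes were at least 2-fold higher and 4891 lower, so 38.3% were higher. That share was 24.9% after rescaling to equal sums, 68.3% when centred on the median gene, which itself lay at -0.59, and 12.9% when centred on ribosomal protein genes. The share of rises thus depended on the scaling.

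**Figure D1:**
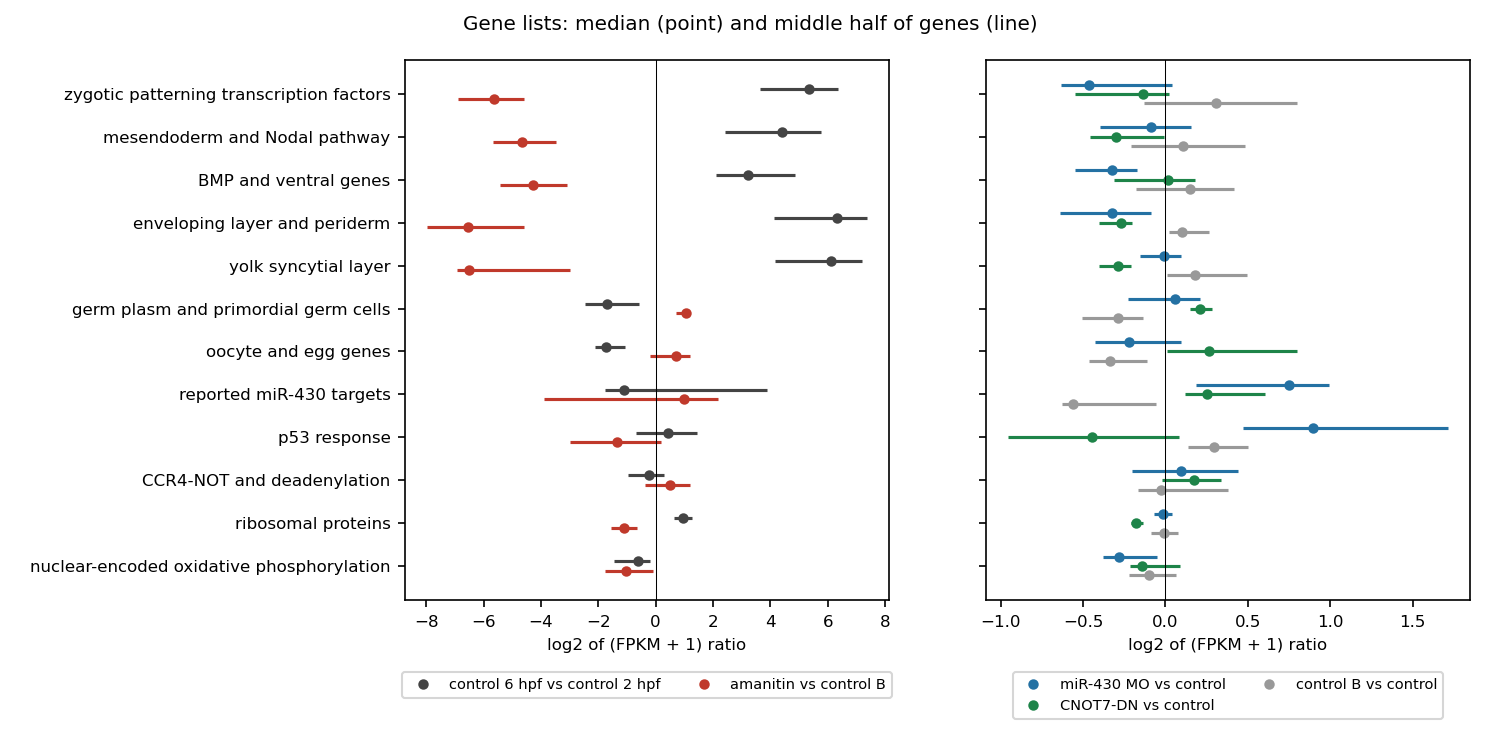
Median log2 ratio of FPKM + 1 (points) and the interquartile range (lines) for gene lists; the left panel shows control 6 hpf against 2 hpf and amanitin against control B, the right panel miR-430 MO, CNOT7-DN and control B against control 6 hpf, on its own scale. Zygotic patterning factors stand at 5.34 with stage and -5.64 with amanitin, and the p53 list at 0.89 in miR-430 MO and -0.44 in CNOT7-DN.

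Amanitin asks which transcripts need transcription by the embryo. Genes with large rises from 2 to 6 hpf were among those lowest against control B: krt18 fell from 1519 to 0.724 FPKM, apoeb from 2036 to 2.03, krt4 from 917 to 0.469, stm from 707 to 0.318, hspb1 from 1829 to 2.98, akap12b from 934 to 1.35 and asb11 from 487 to 0.298. The largest rises were fam129bb (6.55 to 103 FPKM), the mitochondrial import channel tomm40 (10.3 to 149), the tetraspanin cd82b (30.4 to 326), the mitochondrial aminotransferase got2a (6.81 to 80.2), the kinase mknk1 (10.5 to 118), the germ granule gene tdrd6 (23.8 to 239), the cryptochrome cry1b (6.91 to 75.3) and fbxo8 (4.17 to 47.9). In the authors' deposited table q for these genes lay between 0.000105 and 0.00111.

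All the lists of zygotic tissues were low in amanitin. Centring here adds -0.39 on the median gene and 1.11 on ribosomal protein genes. Patterning factors had a median of -5.64. Of 30 measured, 0 rose and 21 fell in the authors' deposited table (0 and 21 adjusted over the list alone). Mesendoderm genes had a median of -4.65. Of 36 measured, 0 rose and 23 fell in the authors' deposited table (0 and 23 adjusted over the list alone). BMP and ventral genes had a median of -4.28. Of 15 measured, 0 rose and 9 fell in the authors' deposited table (0 and 9 adjusted over the list alone). The enveloping layer list had a median of -6.54. Of 16 measured, 0 rose and 10 fell in the authors' deposited table (0 and 10 adjusted over the list alone). The yolk syncytial layer list had a median of -6.50. Of 14 measured, 0 rose and 8 fell in the authors' deposited table (0 and 8 adjusted over the list alone). Germ plasm and egg genes were mostly higher. The germ plasm list had a median of 1.05, or 0.66 centred on the median gene. Of 13 measured, 11 rose and 0 fell in the authors' deposited table (11 and 0 adjusted over the list alone). Among them tdrd7 rose from 17.6 to 81.4 FPKM and buc from 80.5 to 286. Oocyte genes had a median of 0.72, or 0.33 centred on the median gene and 1.82 on ribosomal protein genes. Of 34 measured, 21 rose and 7 fell in the authors' deposited table (21 and 7 adjusted over the list alone). Cyclin A1, ccna1, rose from 278 to 1351 FPKM. Maternal pluripotency factors had a median of 0.28, or -0.11 centred on the median gene. Of 7 measured, 3 rose and 2 fell in the authors' deposited table (3 and 2 adjusted over the list alone). Here eomesa rose from 13 to 111 FPKM and pou5f1 fell from 888 to 413. Reported miR-430 targets had a median of 0.98, or 0.60 centred on the median gene, and an uncentred mean of -0.79. Of 12 measured, 7 rose and 3 fell in the authors' deposited table (7 and 4 adjusted over the list alone).

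Lists of general machinery went different ways. Ribosomal protein genes had a median of -1.11. Of 83 measured, 1 rose and 74 fell in the authors' deposited table (1 and 75 adjusted over the list alone). One of them, rplp1, fell from 204 to 36.8 FPKM. Oxidative phosphorylation genes had a median of -1.03, or 0.077 centred on ribosomal protein genes. Of 77 measured, 9 rose and 47 fell in the authors' deposited table (9 and 47 adjusted over the list alone). Complex I gene ndufs6 fell from 67.6 to 2.14 FPKM and complex IV gene cox7c from 244 to 19.5. Histone genes had a median of -1.11, or -0.0012 centred on ribosomal protein genes. Of 8 measured, 0 rose and 7 fell in the authors' deposited table (0 and 7 adjusted over the list alone). Cell cycle genes had a median of -0.62, or 0.48 centred on ribosomal protein genes. Of 43 measured, 15 rose and 21 fell in the authors' deposited table (15 and 21 adjusted over the list alone). The p53 response list had a median of -1.34, or -0.24 centred likewise. Of 16 measured, 1 rose and 9 fell in the authors' deposited table (1 and 9 adjusted over the list alone). Its member mdm2, the ubiquitin ligase of p53, fell from 449 to 39.6 FPKM. CCR4-NOT genes had a median of 0.49, or 0.10 centred on the median gene, and an uncentred mean of -0.0018. Of 24 measured, 13 rose and 7 fell in the authors' deposited table (13 and 7 adjusted over the list alone). Decay factors had a median of 0.59, or 0.20 centred on it. Of 41 measured, 22 rose and 10 fell in the authors' deposited table (22 and 11 adjusted over the list alone). Members went both ways: lsm14b rose from 46.2 to 402 FPKM and btg1 fell from 72.6 to 1.74.

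In all, 6331 genes rose and 4452 fell of 15235 tested in the authors' deposited table, of which 3147 and 3104 at least 2-fold. Against control 6 hpf in place of control B, 2070 and 2707 of these were again at least 2-fold higher and lower. By size 41.6% of the 3299 higher and 4627 lower genes were higher; the share was 55.4% after rescaling to equal sums, 23.5% centred on the median gene (at 0.39) and 80% centred on ribosomal protein genes.

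Amanitin embryos were also set against the 2 hpf control, a comparison chosen after the table was seen, to follow the RNA of the egg where little new RNA is made. FPKM are relative to all RNA sequenced, so a rise here does not show that RNA was made. RNA that persists while other RNA falls can also gain in FPKM. Among the largest falls were cdca9 (253 to 6.41 FPKM), the coagulation factor f3b (108 to 2.9), COX20 (76.6 to 1.91), btg4 (618 to 22.7), atg12 (51.5 to 1.05), pld1a (52.2 to 1.08), ssna1 (80.7 to 2.37) and cldng (1373 to 55.9). The largest rises included exosc1 (3.48 to 29.1 FPKM), SEC16A (2.92 to 25.2), WNK3 (5.16 to 37.3), srrm1 (9.96 to 65.7) and rbm4.3 (22.5 to 138). In the authors' deposited table q was 0.000123 for each of these genes. Oxidative phosphorylation genes had a median of -1.89. Of 75 measured, 4 rose and 63 fell in the authors' deposited table (4 and 63 adjusted over the list alone). To lists of this comparison centring adds 0.24 on the median gene and 0.054 on ribosomal protein genes. The complex IV gene cox7a2 fell from 86.2 to 4.31 FPKM. Ribosomal protein genes had a median of -0.060, or 0.18 centred on the median gene. Among the 83 measured, 10 rose and 27 fell in the authors' deposited table (10 and 26 adjusted over the list alone). Decay factors lay higher in FPKM, with a median of 0.47. Among the 40 measured, 24 rose and 6 fell in the authors' deposited table (26 and 7 adjusted over the list alone). Cell cycle genes had a median of -0.31. Of 35 measured, 10 rose and 18 fell in the authors' deposited table (10 and 18 adjusted over the list alone). The kinesin kif11 fell from 304 to 26.8 FPKM and the topoisomerase top2a from 222 to 19.5. For oocyte and egg genes the median was -1.27. Among the 34 measured, 2 rose and 29 fell in the authors' deposited table (2 and 29 adjusted over the list alone). For germ plasm genes it was -0.93. Among the 13 measured, 4 rose and 7 fell in the authors' deposited table (4 and 7 adjusted over the list alone). In all, 3100 genes rose and 6160 fell of 13957 tested in the authors' deposited table. By size 16.2% of the differing genes were higher, or 29.9% centred on the median gene (at -0.24).

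Genes at an FPKM of at least 1 at 2 hpf and at least 2-fold lower in control 6 hpf are called cleared (4891 genes). Of these, 4644 fell in the authors' deposited table, and 2295 of them (49.4%) were also at least 2-fold lower in amanitin than at 2 hpf with a q under 0.05 there, btg4, mos and zar1l among them. Another 2307 (49.7%) were less than 2-fold below their level at 2 hpf. Against control B, 1828 (39.4%) rose at least 2-fold in amanitin, tdrd6 and cd82b among them. Genes under an FPKM of 1 at 2 hpf and at least 2-fold higher at 6 hpf are called zygotic (1873 genes). Of the 1789 at an FPKM of at least 1 in amanitin or control B, 97.1% were at least 2-fold lower in amanitin (95% Wilson interval over genes 96.3% to 97.8%), and their median was -2.64. Of these, 842 (47.1%) fell and 7 rose in the authors' deposited table. The cleared genes had a median of 0.80, or 0.41 centred on the median gene.

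The miR-430 morpholino asks what this microRNA, made by the embryo at the onset of transcription, does to the RNA of the egg. Among genes with a symbol on 1 row, the largest rises against control 6 hpf were the anion exchanger slc4a2a (2.72 to 24.2 FPKM), tdrd6 (31.6 to 180.3; ENSDARG00000070052, chromosome 20, 35470063 to 35484057), cenpv (3.61 to 23.9), tp53inp1 (9.18 to 52.3), fam129bb (10.5 to 57.2), the forkhead factor foxo3b (21.1 to 110.2), lnx1 (7.58 to 40.7) and bcl3 (1.92 to 13). The largest falls were hsp70l (22.1 to 1.79 FPKM), the urea transporter slc14a2 (17.7 to 1.42), sox2 (25.9 to 2.5), rpp25l (128 to 22.2), the keratin krt17 (57.8 to 14.5), hsp70.3 (6.27 to 0.975), blf (340.4 to 94.1) and hsp90aa1.2 (43.4 to 11.9). In the authors' deposited table q for these genes lay between 0.000589 and 0.0378. The heat-shock genes were lower in control B as well, at 1.52 FPKM for hsp70l, 1.52 for hsp70.3 and 16.8 for hsp90aa1.2, so hsp70l in miR-430 MO was not lower than in control B, whereas sox2 stood at 46.6 there.

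Genes reported elsewhere as miR-430 targets had a median of 0.75, against -0.56 between the controls. Of 12 measured, 8 rose and 1 fell in the authors' deposited table (8 and 2 adjusted over the list alone). This median lay at percentile 100 of random lists matched on expression. Among them cd82b rose from 57.6 to 178 FPKM, gstm from 29.8 to 91.5, the chemokine cxcl12a from 10.6 to 23 and the Nodal ligand ndr1 from 21.6 to 43.2. Decay factors had a median of 0.075. Of 41 measured, 12 rose and 4 fell in the authors' deposited table (13 and 5 adjusted over the list alone). The helicase ddx6 rose from 43.2 to 99.6 FPKM and lsm1 from 13.5 to 39.9. CCR4-NOT genes had a median of 0.092. Of 24 measured, 8 rose and 2 fell in the authors' deposited table (8 and 3 adjusted over the list alone). The deadenylation adaptor tob1a rose from 93 to 193 FPKM. Against control B the medians of decay factors and CCR4-NOT genes were -0.032 and -0.055, on the other side of 0. Genes of the p53 response, a reported side effect of morpholinos, had a median of 0.89. Of 17 rows measured, 11 rose and 1 fell in the authors' deposited table (11 and 1 adjusted over the list alone). These are rows, and a symbol on several rows counts with each of them. Their median lay at percentile 100, and was 0.54 against control B. No group received a control morpholino. The stress gene sesn1 (ENSDARG00000020693, chromosome 20, 32263285 to 32270038) rose from 15.2 to 102 FPKM, by more than tdrd6, and was left out of the ranking above because its symbol stands on more than 1 row. Other members rose too: phlda3 from 27.1 to 123, the caspase casp8 from 26.1 to 108 and the cell cycle inhibitor cdkn1a from 26.9 to 76.5.

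Of the lists of embryonic tissues, some lay lower in miR-430 MO and others near 0. Centring here adds 0.11 on the median gene and 0.016 on ribosomal protein genes. Zygotic patterning factors had a median of -0.47. Of 29 measured, 3 rose and 15 fell in the authors' deposited table (3 and 16 adjusted over the list alone). Here eve1 fell from 62.1 to 23.7 FPKM and cdx4 from 16.4 to 7.48. Enveloping layer genes had a median of -0.33. Of 16 measured, 0 rose and 7 fell in the authors' deposited table (0 and 9 adjusted over the list alone). BMP and ventral genes had a median of -0.33. Of 15 measured, 1 rose and 6 fell in the authors' deposited table (2 and 8 adjusted over the list alone). Mesendoderm genes had a median of -0.087, or 0.024 centred on the median gene. Of 36 measured, 4 rose and 7 fell in the authors' deposited table (4 and 7 adjusted over the list alone). Yolk syncytial layer genes had a median of -0.0085, or 0.10 centred (its sign turned under each scaling), and an uncentred mean of 0.033. Of 14 measured, 2 rose and 1 fell in the authors' deposited table (2 and 2 adjusted over the list alone). Oxidative phosphorylation genes had a median of -0.28. Of 77 measured, 2 rose and 8 fell in the authors' deposited table (1 and 5 adjusted over the list alone). Zinc finger genes had a median of -0.22. Of 117 measured, 5 rose and 33 fell in the authors' deposited table (6 and 33 adjusted over the list alone). Oocyte genes had a median of -0.22, but 0.13 against control B. Of 34 measured, 2 rose and 9 fell in the authors' deposited table (2 and 10 adjusted over the list alone). The germ plasm list, which holds tdrd6, had a median of 0.056, at percentile 89.23 and within the range of most random lists. Of 13 measured, 2 rose and 2 fell in the authors' deposited table (2 and 2 adjusted over the list alone). In all, 1346 genes rose and 2296 fell of 14301 tested in the authors' deposited table, and 319 and 188 of these differed at least 2-fold. Of the latter, 231 higher and 85 lower genes were also at least 2-fold apart from control B. The 4.92% of genes at least 2-fold apart compares with 3.91% between the controls. These were 415 higher and 353 lower genes, and against control B they were 656 and 840. Of those apart from control 6 hpf 54% were higher, or 69% centred on the median gene (at -0.11).

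CNOT7-DN asks what deadenylation by CNOT7 does. Apart from cnot7 itself, the largest rises against control 6 hpf were rims1a (2.14 to 12.5 FPKM), the Polycomb gene bmi1b (12 to 41.8), ccdc82 (25.4 to 83.6), SAMD5 (3.15 to 12.2), the mitochondrial ribosomal gene mrps30 (10.5 to 34.7), sinup (25.4 to 80.8) and the augmin subunit haus6 (49.3 to 151). The largest falls were hsp70l (22.1 to 0.639 FPKM), hsp70.3 (6.27 to 0.489), hsp90aa1.2 (43.4 to 9.69), sp5l (23.3 to 5.6), RNF14 (5 of 5) (7.49 to 1.32), sox2 (25.9 to 6.53), the apolipoprotein apoa1b (8.46 to 1.75) and gdpd3a (5.86 to 1.15). In the authors' deposited table q for these genes lay between 0.000996 and 0.0018. In control B, hsp70l was at 1.52 FPKM, sp5l at 91.6, sox2 at 46.6 and apoa1b at 38.

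Egg genes were higher in CNOT7-DN. Centring here adds -0.037 on the median gene and 0.18 on ribosomal protein genes. Oocyte and egg genes had a median of 0.27. Of 34 measured, 12 rose and 0 fell in the authors' deposited table (14 and 0 adjusted over the list alone). Their median lay at percentile 100. The same list differed by more between the controls, where control B lay at a median of -0.34 against control 6 hpf (percentile 0). The egg gene org rose from 92.6 to 262 FPKM, the maternal linker histone h1m from 314 to 756, zar1l from 56.6 to 133 and the claudin cldnd from 245 to 558. Reported miR-430 targets had a median of 0.25, and they too differed by more between the controls (-0.56). Of 12 measured, 5 rose and 1 fell in the authors' deposited table (5 and 1 adjusted over the list alone). CCR4-NOT genes, cnot7 among them, had a median of 0.18. Of 24 measured, 6 rose and 1 fell in the authors' deposited table (8 and 1 adjusted over the list alone). Germ plasm genes had a median of 0.21, at percentile 94.45 and within the range of most random lists. This list also differed by more between the controls (-0.29). Of 13 measured, 2 rose and 0 fell in the authors' deposited table (2 and 0 adjusted over the list alone). Zinc finger genes had a median of 0.11, at percentile 93.31 and likewise within the range of most random lists. Of 116 measured, 13 rose and 1 fell in the authors' deposited table (13 and 1 adjusted over the list alone). Over all genes 1465 of 14439 tested rose. The p53 response and several lists of embryonic tissues were lower. The p53 list had a median of -0.44. Of 16 measured, 1 rose and 8 fell in the authors' deposited table (1 and 9 adjusted over the list alone). The inhibitor cdkn1a fell from 26.9 to 9.71 FPKM, the apoptosis gene bbc3 from 9.06 to 2.94 and gadd45aa from 12.7 to 4.81. Mesendoderm genes had a median of -0.30. Of 36 measured, 1 rose and 13 fell in the authors' deposited table (1 and 16 adjusted over the list alone). The apelin receptor aplnrb fell from 86.1 to 41.2 FPKM and mespaa from 9.93 to 4.73. Enveloping layer genes had a median of -0.27. Of 16 measured, 0 rose and 5 fell in the authors' deposited table (0 and 6 adjusted over the list alone). Yolk syncytial layer genes had a median of -0.29. Of 13 measured, 1 rose and 4 fell in the authors' deposited table (1 and 8 adjusted over the list alone). Centred on ribosomal protein genes the medians were -0.12 for mesendoderm, -0.095 for the enveloping layer and -0.11 for the yolk syncytial layer. BMP and ventral genes had a median of 0.017, or -0.021 centred on the median gene, and an uncentred mean of -0.080. Of 15 measured, 2 rose and 3 fell in the authors' deposited table (2 and 4 adjusted over the list alone). Zygotic patterning factors had a median of -0.13, which became 0.042 when centred on ribosomal protein genes. Of 29 measured, 3 rose and 13 fell in the authors' deposited table (3 and 13 adjusted over the list alone). Ribosomal protein genes had a median of -0.18. Of 83 measured, 0 rose and 0 fell in the authors' deposited table (0 and 0 adjusted over the list alone).

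In all, 1465 genes rose and 577 fell of 14439 tested in the authors' deposited table, of which 131 and 72 at least 2-fold; 119 and 64 of these were also at least 2-fold apart from control B. By size alone 2.77% of genes were at least 2-fold apart, against 3.91% between the controls. These were 236 higher and 197 lower genes, and against control B they were 992 and 785. Of the genes at least 2-fold apart 54.5% were higher, or 78.7% centred on ribosomal protein genes.

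The cleared genes moved in both injections, by different measures. In CNOT7-DN they had a median of 0.29, 86.1% lay above 0, and 1121 rose and 6 fell of 4587 in the authors' deposited table. Genes kept within 2-fold from 2 to 6 hpf had a median of -0.014, or 0.16 centred on ribosomal protein genes, and zygotic genes one of -0.24. The same centring gave -0.061 for zygotic and 0.47 for cleared genes. In miR-430 MO the cleared genes had a median of -0.20, and 529 rose and 936 fell of 4488 in the authors' deposited table. Of these 4.57% were at least 2-fold higher (95% Wilson interval over genes 3.99% to 5.22%), against 0.699% of kept genes and 0.715% of cleared genes between the controls. In CNOT7-DN 3.38% of cleared genes were at least 2-fold higher (2.89% to 3.94%). Against control B the shares were 8.57% in miR-430 MO and 16.1% in CNOT7-DN, so which injection had the larger share depended on the control. With cleared genes selected on control B, and the injections compared with control 6 hpf, injections and amanitin have separate controls. Among genes that rose at least 2-fold in amanitin 7.99% were then at least 2-fold higher in miR-430 MO and 2.83% in CNOT7-DN, and among the other cleared genes 0.547% and 2.38%. The miR-430 MO median turned to 0.046 against control B. Between the controls cleared genes lay at -0.25 and zygotic genes at 0.21. Zygotic genes in miR-430 MO had a median of -0.21, or -0.44 against control B. Among cleared genes that rose at least 2-fold in amanitin, 26.4% of 1828 rose in miR-430 MO and 32.3% in CNOT7-DN in the authors' deposited table. Among those also lower in amanitin than at 2 hpf, 1.79% of 2295 rose in miR-430 MO and 22.6% in CNOT7-DN in the same table.

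**Figure D2:**
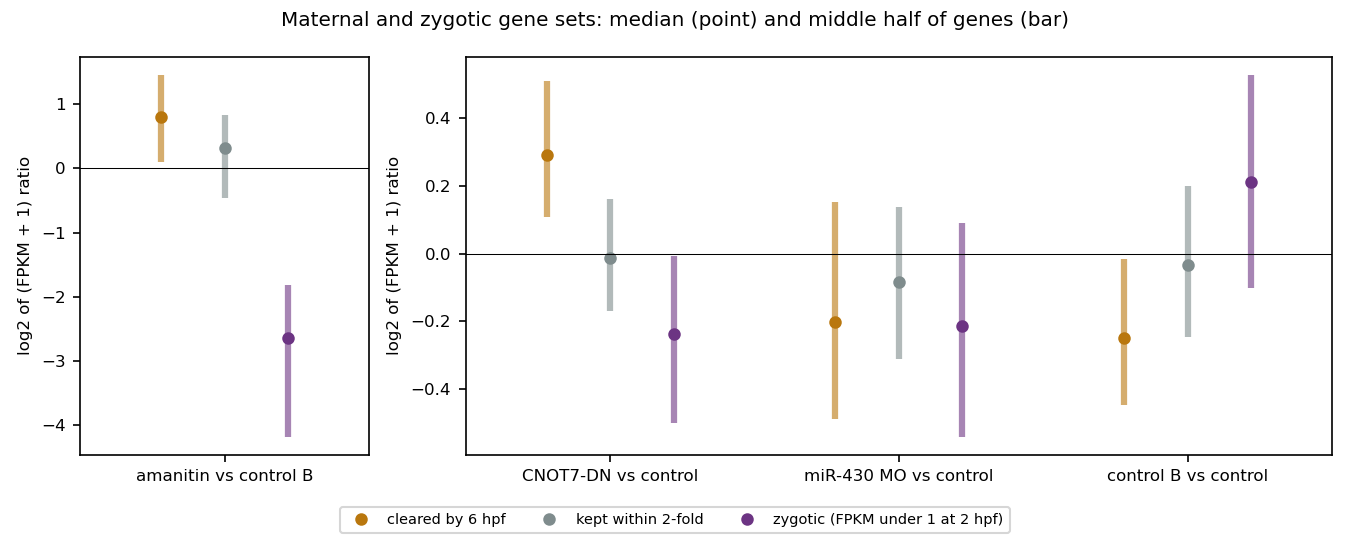
Log2 ratio of FPKM + 1 of cleared genes, genes kept within 2-fold and zygotic genes, under an FPKM of 1 at 2 hpf (points, medians; bars, interquartile range over genes) in amanitin against control B (left, own scale) and in CNOT7-DN, miR-430 MO and control B against control 6 hpf (right). Cleared genes stand at 0.80 in amanitin, 0.29 in CNOT7-DN, -0.20 in miR-430 MO and -0.25 between the controls.

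The injections overlapped in part. Genes at least 2-fold higher in both miR-430 MO and CNOT7-DN numbered 41, where independent lists would share 4.47, and 66 were lower in both, against 4.53. Both comparisons use control 6 hpf, which independent lists leave out of account. With control B for miR-430 MO, 34 and 60 were shared, where independent lists would share 7.92 and 9.76. Across genes, which are not independent replicates, the changes correlated at r = 0.22 (Spearman 0.036), with a covariance of 0.0535. A simulated shared control gave 0.50 and 0.124. The simulation gave every group the same spread, which by itself fixes r near 0.50. It also took the whole difference between the controls as noise. It therefore cannot tell how much of the sharing comes from the shared control. With control B for miR-430 MO r was 0.16, and with control B for CNOT7-DN it was -0.019. Separate controls were used for amanitin: 196 genes were higher in both miR-430 MO and amanitin, where independent lists would share 77.3, and 189 were lower in both (92.7). CNOT7-DN and amanitin shared 82 higher (42.7) and 140 lower genes (46.8).

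**Figure D3:**
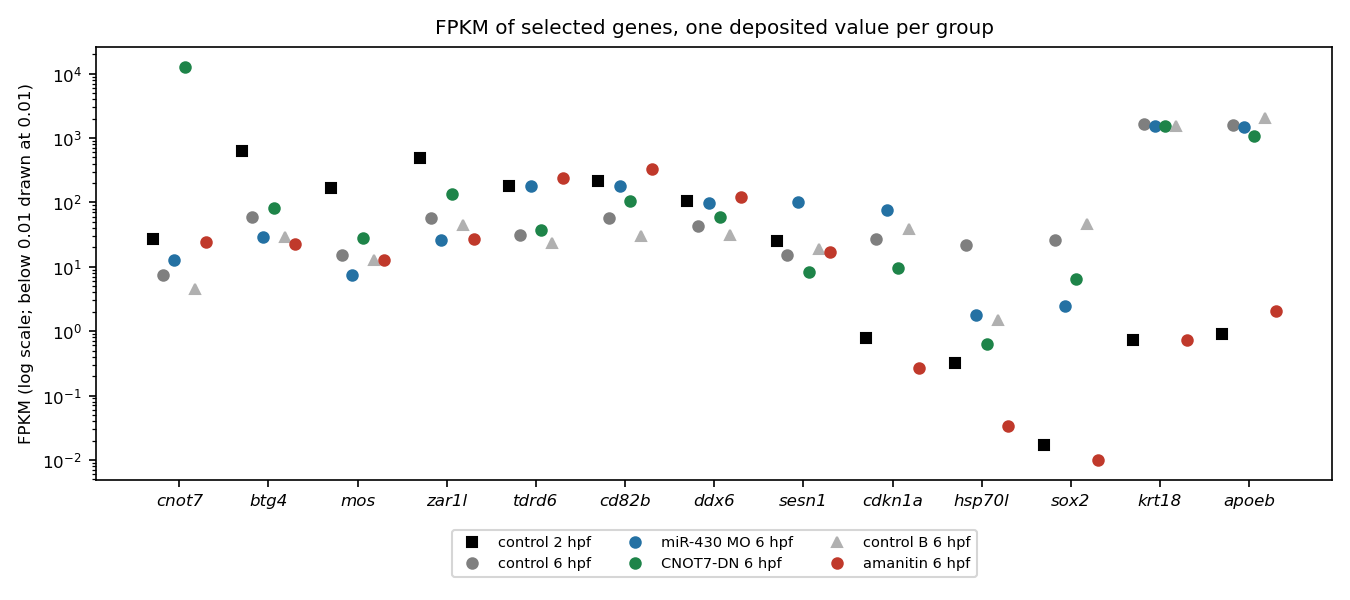
FPKM of single genes on a log axis, one point per group (squares, 2 hpf; circles, 6 hpf groups; triangles, control B), with values under the axis minimum drawn at it. The egg gene btg4 stands at 618 FPKM at 2 hpf and 22.7 in amanitin, tdrd6 at 177 and 239, and krt18 at 1636 in control 6 hpf and 0.724 in amanitin.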

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

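The comparison of amanitin with 2 hpf, selection of sets on both controls, the p53 list without its member among the named largest rises of miR-430 MO, the check of called genes against control B and list medians under equal sums and ribosomal centring were chosen after seeing the data. The pattern of small RNA names was also corrected then. Counts of genes at least 2-fold apart depend on the settings. Of the counts and set medians, 121 alternative values stayed within 1.5-fold, or within the difference between the controls, 88 did not and 1 turned sign. Among cleared and zygotic medians of the injections only that of cleared genes in miR-430 MO turned. Genes kept within 2-fold turned when centred on the median gene, to 0.027 in miR-430 MO, -0.067 in amanitin and 0.17 in amanitin against 2 hpf, with 0.016 between the controls. In CNOT7-DN they turned to 0.16 centred on ribosomal protein genes and 0.0075 with equal sums. For lists, shares of set genes and single genes 705 values stayed close, 443 moved further and 8 that were called turned sign. Close meant within the difference between the controls, or for shares within the Wilson interval of the main value. With uncalled ones included, 40 of 485 list values and 7 of 629 gene values changed sign. Of 132 list medians, 41 changed sign under some scaling. A larger pseudocount, fold or minimum counts fewer genes by construction; other causes were not tested.

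Numbers of genes higher and lower with a pseudocount of 5 were 1789 and 3002 for 6 against 2 hpf, 196 and 99 for miR-430 MO, 106 and 67 for CNOT7-DN, 1900 and 2702 for amanitin, 131 and 75 for control B and 479 and 2631 for amanitin against 2 hpf. At 4-fold they were 1507 and 870 for 6 against 2 hpf, 58 and 44 for miR-430 MO, 46 and 39 for CNOT7-DN, 516 and 2404 for amanitin, 54 and 40 for control B and 128 and 1501 for amanitin against 2 hpf. At 1.5-fold they were 7436 lower for 6 against 2 hpf, 1117 and 1908 for miR-430 MO, 1159 and 614 for CNOT7-DN, 5630 higher for amanitin, 1404 and 1238 for control B and 2126 higher for amanitin against 2 hpf. With a pseudocount of 0.1 they were 650 and 785 for miR-430 MO, 441 and 377 for CNOT7-DN and 804 and 499 for control B. Genes at FPKM of at least 5 left 126 lower for CNOT7-DN and 163 for control B. Unique symbols left 1682 higher for 6 against 2 hpf, 192 lower for miR-430 MO, 149 and 92 for CNOT7-DN, 2860 lower for amanitin and 207 and 113 for control B.

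Centred on ribosomal protein genes the numbers were 1542 and 10391 for 6 against 2 hpf, 454 and 123 for CNOT7-DN and 8947 and 2242 for amanitin. Rescaling to equal sums gave 7634 lower for 6 against 2 hpf and 5153 higher for amanitin, and centring on the median gene 2027 lower for 6 against 2 hpf, 1716 higher for amanitin and 1383 higher for amanitin against 2 hpf. Against the other 6 hpf control, miR-430 MO had 656 and 840 and CNOT7-DN 992 and 785; the cause was not tested.

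Requiring 2-fold as well as the authors' q left 2027 and 4644 genes for 6 against 2 hpf, 319 and 188 for miR-430 MO, 131 and 72 for CNOT7-DN, 3147 higher for amanitin and 668 and 3732 for amanitin against 2 hpf. At 1.5-fold, shared higher and lower genes were 200 and 209 for miR-430 MO and CNOT7-DN, 608 and 965 for miR-430 MO and amanitin, and 627 and 459 for CNOT7-DN and amanitin. With control B for CNOT7-DN, 72 higher genes were shared with miR-430 MO.

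Against the other control the cleared median of miR-430 MO turned to 0.046, and its zygotic median was -0.44. The amanitin zygotic median was -2.29 against the other control, -2.29 with selection on control B, -3.02 centred on the median gene, -3.93 at FPKM of at least 5, -3.85 with 4-fold selection and -4.83 with a pseudocount of 0.1. The amanitin cleared median was 0.41 centred and 0.54 with 4-fold selection. Lists of miR-430 MO that turned against control B were oocyte genes (0.13), CCR4-NOT (-0.055) and decay factors (-0.032); hsp70l became 0.15 and histh1l -0.011. Centring turned solute carriers in miR-430 MO (0.058), ribosomal proteins in amanitin against 2 hpf (0.18) and cnot8 from 2 to 6 hpf (0.14), through the amount it adds to each ratio. The cause of the turns against control B was not tested. Without tp53inp1, its member among the named largest rises, the p53 list had a median of 0.76 in miR-430 MO. The gene sesn1, which rose by more, was still in the list.

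No paired analysis was possible because the columns give 1 value per group. For the same reason leaving out each replicate, a replicate block, count tests and limma were not run. The planned checks of codon usage, 3 prime UTR length and miR-430 seed sites were not run, as no transcript sequences were used here. Depth is unknown, so the precision of low FPKM is not known either.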

Other observations

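All tests of explanations in this part were chosen after the results they measure had been seen. Small nucleolar RNA was more abundant at 6 hpf and less so with amanitin. How row length affects the FPKM of such short RNA was not tested. Summed FPKM of snoRNA and scaRNA rows was 9117 at 2 hpf, 105179 in control 6 hpf, 124730 in control B and 17789 in amanitin. There were 250 such rows, 198 of them above 0. From 2 to 6 hpf 20 of these rows rose and 1 fell in the authors' deposited table, and with amanitin 1 rose and 23 fell. The 7SK row stood at 395, 25980.1, 27214 and 10103 FPKM in the same groups. Signal recognition particle RNA summed to 55922, 96188, 71114 and 93271. Precursor rows of miR-430 summed to 5.27 at 2 hpf, 9551 in control 6 hpf, 10709 in miR-430 MO, 11735 in CNOT7-DN, 3299 in control B and 51.8 in amanitin. Of these 53 rows only 3 were above 0. From 2 to 6 hpf and with amanitin, 0 of them rose and 0 fell in the authors' deposited table. All 37 rows on the mitochondrial chromosome are listed at 0 in every group.

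Lists set up as checks gave the following. Heat shock and interferon genes had a median of 1.16 from 2 to 6 hpf. Of 16 measured, 9 rose and 2 fell in the authors' deposited table (9 and 2 adjusted over the list alone). In miR-430 MO they had a median of -0.15. Of 16 measured, 3 rose and 5 fell in the authors' deposited table (4 and 5 adjusted over the list alone). In CNOT7-DN they had a median of -0.24. Of 16 measured, 2 rose and 5 fell in the authors' deposited table (3 and 6 adjusted over the list alone). In amanitin they had a median of -1.15. Of 15 measured, 1 rose and 7 fell in the authors' deposited table (1 and 7 adjusted over the list alone). The heat-shock gene hsp70l was at 1.52 FPKM in control B against 22.1 in control 6 hpf, so its fall in miR-430 MO rests on control 6 hpf. Later-stage markers, few of them measured, had a median of -1.30 from 2 to 6 hpf and a mean of -0.068. Of 7 measured, 2 rose and 4 fell in the authors' deposited table (2 and 4 adjusted over the list alone). In CNOT7-DN they had a median of 0.25 and a mean of -0.046. Of 7 measured, 1 rose and 1 fell in the authors' deposited table (1 and 1 adjusted over the list alone). In miR-430 MO they had a median of -0.31. Of 7 measured, 1 rose and 1 fell in the authors' deposited table (1 and 1 adjusted over the list alone). Control B lay at 0.51 against control 6 hpf for the 6 measured there. So few genes were not used to judge stage. Adult tissue markers had a median of 1.84 from 2 to 6 hpf. Of 5 measured, 2 rose and 1 fell in the authors' deposited table (2 and 1 adjusted over the list alone).

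Cleared genes higher and zygotic genes lower is also what younger embryos would show. Cleared genes selected on control 6 hpf had a median of 0.53 in CNOT7-DN against control B, where selection does not favour a rise. They thus lay above either control. Since control B itself lay at -0.25 against control 6 hpf, that value was largely fixed beforehand. It cannot show which control lies apart. Delay was tested by how much of the change from 2 to 6 hpf was undone, with control 6 hpf in both pairs and the assumption, not tested, that the controls differ in stage. CNOT7-DN undid 16.5% in cleared and 7.51% in zygotic genes, and control 6 hpf against control B 14.8% and 8.72%. The ratio of the CNOT7-DN pair to the control pair was 1.29 (95% of resampled genes 1.12 to 1.48). A value above 1 means that CNOT7-DN undid relatively more in cleared genes. Genes were resampled separately for each pair though both hold the same genes, so the interval ignores that pairing. Under the assumption on stage, an earlier stage may account for part of the pattern. Weaker deadenylation stays open beside it, as untested.

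The p53 list was higher in miR-430 MO against either control, with a median of 0.54 against control B, which argues against control 6 hpf as the whole source. CNOT7-DN embryos were injected too and had a median of -0.44, so the list was not higher in every injected group. Other effects of CNOT7-DN on these genes could not be separated from injection. This group therefore does not exclude a response to injection. A response to the morpholino as a reagent and one to loss of miR-430 could both give this list, and without a control morpholino among the groups neither was tested.

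Cleared genes higher in miR-430 MO lay mostly, not wholly, among those higher in amanitin. With cleared genes selected on control B and miR-430 MO compared with control 6 hpf, 7.99% of the 2189 genes that rose at least 2-fold in amanitin were at least 2-fold higher in miR-430 MO, against 0.547% of the other 3108, a ratio of 14.6. Across the other choices of control the ratio was 8.94 to 14, so selection on the shared control is not its whole source. In CNOT7-DN the ratio was 1.19 in the same setting and 1.2 on control 6 hpf alone, but 2.07 and 2.21 against control B, which amanitin shares, and its difference from miR-430 MO was not tested. The values are consistent with clearance by a microRNA that the embryo makes itself, a hypothesis found and tested on the same data; seed sites were not searched.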
